A study of Mus musculus with 7 samples.

How the data were processed

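RNA from primary mouse keratinocytes that had received an empty MSCV retrovirus (Vector, 3 samples) or one carrying HRasV12 (Ras, 4 samples) was measured on 7 1-colour Agilent arrays, 1 per sample. Replicate numbers are those of the labels, and the numbers in the scanner file names follow a different order. Per the labels, RNA was taken 6 days after infection and 100 ng of it was labelled with Cy3. Per the file headers, the deposited scanner files hold spot intensity on a linear scale from Feature Extraction 10.7.3.1, background-subtracted and detrended within each array and not normalized between arrays. Each file gives 59305 non-control spots for 55681 probes. Between 49.9% and 55.4% of the probes were well above background on an array, 0 spots were saturated, and 157 to 250 spots per array carried an outlier mark. The median SD of probes spotted 10 times was 0.048 to 0.062 on the log2 scale. The number of arrays limits the precision.

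The authors also deposited a table of processed values on the log2 scale, which had nearly the same sorted values in each column, so they had been quantile-normalized over all spots. Within each array these values rose in step with mean signal minus local background, with the direction of the scanner files. The method of background correction is not stated and stays unknown. The median of each column was 6.755, except 6.754 for Vector replicate 2. This table served as an alternative only.

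Signals were read and fitted in R 4.3.3 with limma 3.58.1 and data.table in version 1.17.8, and drawn with matplotlib 3.10.9. The processed signal of each spot was put on the log2 scale and each array's 75th percentile over non-control probes was subtracted. Control spots and spots with an outlier mark were left out, and spots of a probe were averaged. A probe was kept if it was well above background on at least 3 of the 7 arrays, which left 30627 probes. Each gene was read by its brightest kept probe, chosen without the groups, which gave 22478 genes, 5696 of them with several probes. Of 2630 genes past the test with several kept probes, 253 had kept probes of differing sign. At least 1 array was missing for 70 genes. Names came from the RefSeq accession in the files for 14027 tested genes, from a symbol in the RefSeq gene file for 1870 and from a synonym for 259, and 6322 kept the name in the files. Probe coordinates are those of the file headers' design, on mm9. No annotation of that build was used here, so the exon or untranslated region under a probe is not given.

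Ras and Vector were compared per gene with limma's lmFit and eBayes, as a two-sided moderated test with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Counts of genes are also given at a change of at least 2-fold. A gene with no probe well above background on any array of a group has only a bound on its ratio. This held for 417 genes called higher, dim in Vector, and 298 called lower, dim in Ras. Arrays were assigned to slides by the scan date in the file headers, taking arrays with the same scan date as 1 slide. This gave 2 slides, with 2 Vector and 2 Ras arrays on slide 1 and 1 Vector and 2 Ras arrays on slide 2. Slide was therefore also used as a fixed block, and each slide was fitted alone. Arrays of a group correlated at 0.995 to 0.997 on the same slide and at 0.985 to 0.990 across slides. Arrays of different groups correlated at 0.926 to 0.945.

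The groups, tests, alternatives, 32 gene lists and the rule for the genes named were written down before the data were examined. Lists of at least 3 tested members covered ERK targets, EGF receptor ligands, cell cycle inhibitors, p53 targets, S phase, mitosis, secreted cytokines, secreted proteases and lysosomal hydrolases. Others covered spinous, cornified, stress keratin and SPRR, simple keratin, basal, junction, alarmin, NF-kB, interferon, TGF-beta, Notch and Wnt genes. The rest covered glycolysis, oxidative phosphorylation, cholesterol, fatty acid and PPAR, unfolded protein, NRF2 and ribosome biogenesis genes, and markers of fibroblasts, melanocytes, leukocytes and endothelium. Some genes belong to more than 1 list. Each list was set against all other tested genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, on genes with values on all arrays, which left 20 of 21 ribosome biogenesis genes. List tests and means use fitted values, dim genes included, and means are also given with dim genes at their bound. The mean of each list was tested with an exact two-sided permutation test over the 35 splits of the arrays.

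Named genes were Hras, the 12 genes per direction with the largest change among called genes well above background on all arrays with separate groups and a proper symbol, and up to 5 per direction by their bound. From each list the 3 members per direction with the smallest adjusted p could be named, or 2 where none passed. A fixed set of senescence, keratin and control genes was always considered. The values of 1 gene named by this rule are not reported here.

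Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, the authors' processed values, no filter on dim probes, a filter requiring all 7 arrays, keeping spots with an outlier mark, and the mean of a gene's probes. Further ones were slide as a block, each slide alone, the replicate number as a block, a variance trend with robust fitting, an unmoderated two-sample test, leaving out each sample in turn, and for lists an estimated correlation and the rotation test fry. The slide block together with an estimated correlation was added after the data were seen.

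The fit was tested on simulated data for 30537 probes, 200 of them changed, 50 at each size. It recovered 10% of those changed by 0.5 on the log2 scale, 56% at 1, 86% at 2 and 92% at 4. It called 6 of 30337 unchanged probes. A simulated list of 25 probes shifted by 1 had a camera adjusted p = 2.14e-53 with the preset and 0.00061 with an estimated correlation, and 0 of 30 unshifted lists were called. The simulated noise was independent between probes and held no slide difference, whereas the estimated correlation of the real lists reached 0.491. The 200 changed probes were also a far smaller share than the 45.4% of genes called in the data. The simulation therefore cannot show how often camera calls unshifted lists in the real data.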

Results

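Primary keratinocytes, the epithelial cells of the epidermis, were taken from mice and given either an empty MSCV retrovirus or the same virus carrying HRasV12, an always-active form of the small GTPase Hras. The title of the series concerns the senescence that an oncogene brings on, and the comparison asks how transcript levels differ between the groups. Total RNA was collected 6 days after infection, and 100 ng of it was labelled for each 1-colour Agilent array. The empty-virus group, called Vector, had 3 samples and the HRasV12 group, called Ras, had 4. Between 27776 and 30831 of the 55681 probes were well above background on each array, and 0 spots were saturated. With 7 arrays in all, their number limits the precision. The labels do not say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. Levels below are log2 signals relative to the 75th percentile of their array, changes are Ras minus Vector on the log2 scale, and adjusted p-values are from limma unless another test is named.

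Hras itself, the gene whose active form was introduced, was lower on the Ras arrays. Its brighter probe, on chromosome 7 from 148377296 to 148377355 of mm9, gave 4.88 ± 0.14 (SD, n = 3) in Vector and 4.09 ± 0.25 (SD, n = 4) in Ras. The change was -0.79 (SE 0.15, adjusted p = 0.00479), with -0.73 when slide is a block, -0.65 on slide 1 and -0.85 on slide 2. The other Hras probe above background changed by -0.67 (SE 0.16), and the third was not well above background on any array. The labels give neither the species nor the sequence of the introduced gene, so a mouse probe may not read it, and these values check nothing about the labels.

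Ras and Vector cells differed across much of the transcriptome. Spp1, the secreted matrix protein osteopontin, rose by 8.19 (SE 0.09, adjusted p = 4.61e-08), from -2.50 ± 0.07 (SD, n = 3) to 5.69 ± 0.12 (SD, n = 4). Krt8 and Krt18, the paired keratins of simple epithelia, rose by 7.38 (SE 0.39) and 6.18 (SE 0.46). Spink5, a protease inhibitor of the upper epidermis, changed by -8.28 (SE 0.09, adjusted p = 4.61e-08), and Krt16, a keratin of stressed epidermis, by -7.03 (SE 0.26). Of 22478 genes tested, 5374 were higher and 4821 lower in Ras at an adjusted p below 0.05, together 45.4%. At least 2-fold changes were found for 2134 genes that rose and 1977 that fell. By their scan dates the arrays came from 2 slides that each held both groups. With slide as a block, 7258 genes rose and 6374 fell. On slide 1 alone, with 2 arrays per group, the counts were 6214 and 5167. On slide 2 they were 4116 and 3564, where the lone Vector array is assumed to vary like the Ras arrays. The Ras and Vector values did not overlap at all for 11429 genes, 50.8% of those tested, where chance gives 5.7%.

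**Figure D1:**
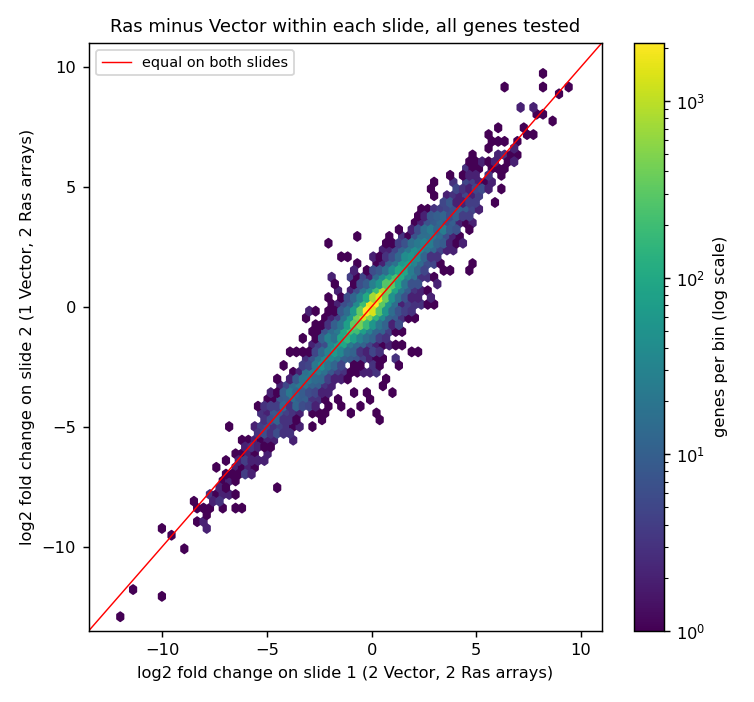
Log2 fold change, Ras minus Vector, on slide 1 (horizontal axis, 2 Vector and 2 Ras arrays) against slide 2 (vertical axis, 1 Vector and 2 Ras arrays) for 22467 genes, with colour giving the number of genes per bin on a log scale and the red line equal values. Across genes, which are not independent replicates, Pearson's r was 0.946 and Spearman's rho 0.877.

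The genes with the largest increases, among those well above background on every array, also included Ctla2a and Ctla2b, near-identical genes for cysteine protease inhibitors. They rose by 8.67 (SE 0.42) and 8.54 (SE 0.33), and a probe for one may read the other. Lcn2, the iron-binding antimicrobial lipocalin 2, rose by 7.96 (SE 0.22), and Cp, the copper protein ceruloplasmin, by 6.89 (SE 0.11). Grem1, a secreted antagonist of bone morphogenetic proteins, rose by 6.37 (SE 0.12). Vegfc, a growth factor of lymphatic vessels, rose by 6.06 (SE 0.10). Srgap3, a GTPase-activating protein, rose by 6.17 (SE 0.30), with 4.52 at the lowest of its 3 probes, and Rgs16, a regulator of G-protein signalling, by 6.06 (SE 0.15). The pseudogene Krt8-ps, whose probe may read Krt8, rose by 7.44 (SE 0.36). Where a gene was not well above background on any array of a group, the ratio is only a bound, with each such array set to the higher of the gene's own signal and the lowest signal of any probe well above background. These bounds hold for this scaling only. With normexp correction and with the authors' processed values, the fitted folds of all 21 named genes with a bound lay below it, for Mmp9 down to 63.3-fold. By its bound Mmp9, the gelatinase that degrades type IV collagen, was at least 214-fold higher in Ras. Lilrb4a was at least 176-fold higher at its brighter probe, with a fitted change of 6.02 at the other, Zfpm2 at least 113-fold, Rasgrp3, an activator of Ras proteins, at least 94.9-fold, and the casein gene Csn3 at least 88.6-fold.

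The largest decreases, also among genes well above background on every array, included Spink5 and Krt16. Calm4, a calmodulin-like protein of differentiating keratinocytes, changed by -8.29 (SE 0.28), and Cnfn, the cornified envelope protein cornifelin, by -7.80 (SE 0.25). Cdsn, the corneodesmosome protein corneodesmosin, changed by -7.04 (SE 0.15) and Sprr1a, a small proline-rich envelope precursor, by -6.89 (SE 0.17). Igfbp2, an insulin-like growth factor binding protein, changed by -7.42 (SE 0.12). Also among the 12 largest were Tmem45a at -7.81 (SE 0.08), the membrane protease Tmprss4 at -7.48 (SE 0.19), the cystatin Stfa1 at -7.08 (SE 0.19), Sostdc1 at -6.80 (SE 0.19) and Ly6d at -6.68 (SE 0.11). Flg, the precursor of filaggrin on chromosome 3 from 93097529 to 93097588, was at least 1196-fold lower in Ras. Krtdap, a protein of differentiating keratinocytes, was at least 1077-fold lower. The envelope genes Lce1a1 and Sprr2g were at least 211-fold and 123-fold lower, and Il1f5, the interleukin 36 receptor antagonist, at least 152-fold. The housekeeping genes Actb and Gapdh changed by -0.04 (adjusted p = 0.778) and 0.05 (adjusted p = 0.598). The sign of Actb turned with quantile normalization, at 0.18 (adjusted p = 0.0472), where its alternatives ranged from 0.0472 to 0.959. Gapdh then gave 0.30 (adjusted p = 0.0119), and its alternatives ranged from 0.00314 to 0.891.

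**Figure D2:**
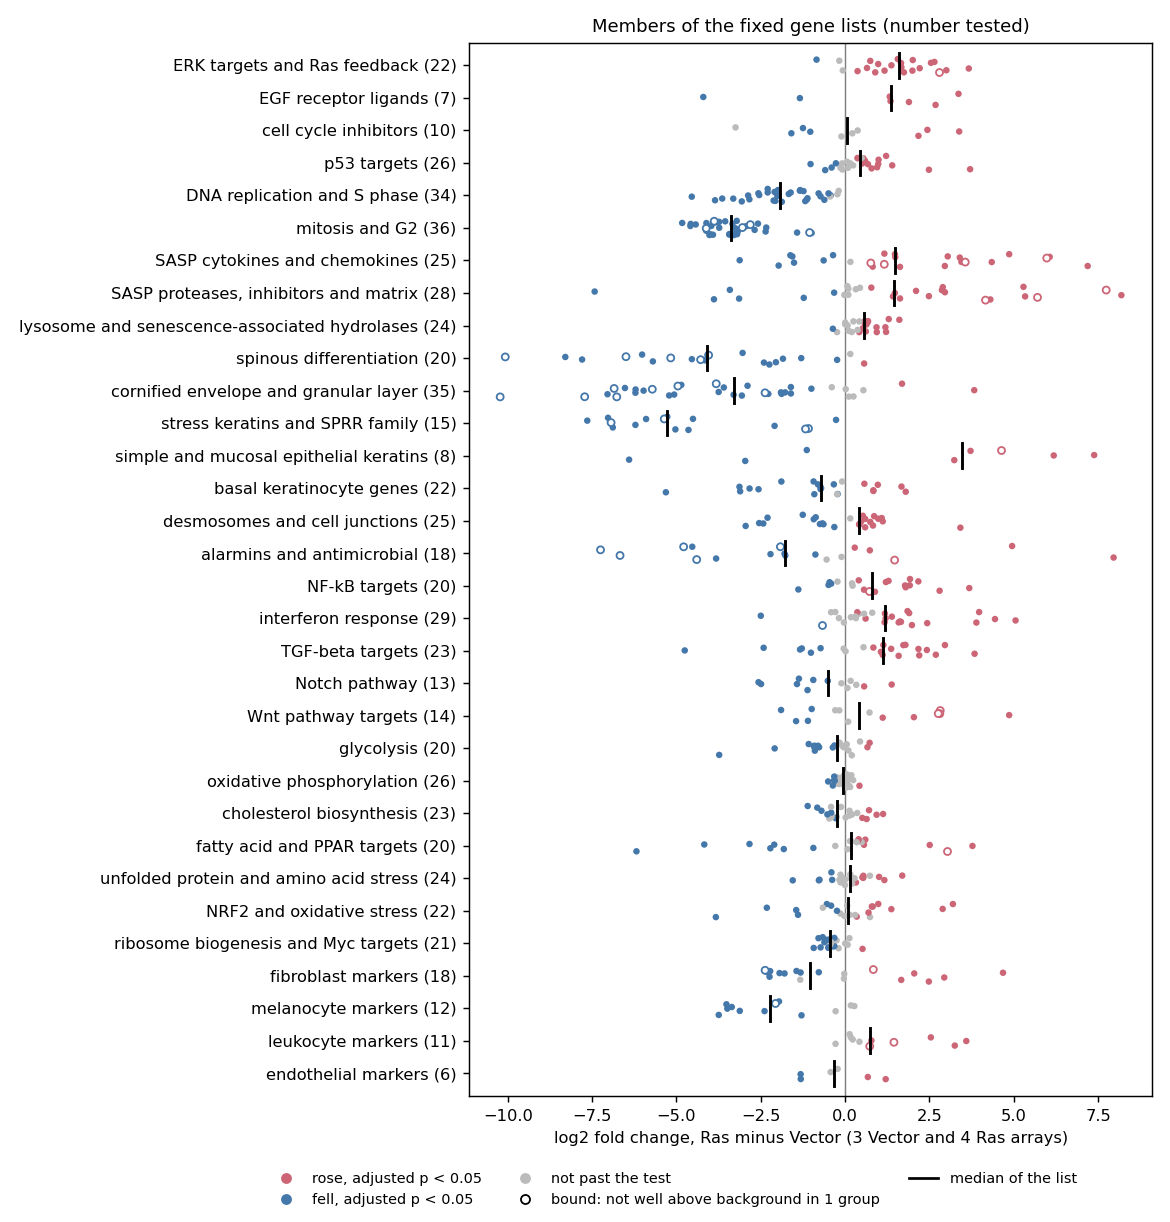
Log2 fold change, Ras minus Vector, of each tested member of the 32 gene lists (horizontal axis, 3 Vector and 4 Ras arrays), coloured by whether the member rose, fell or did not pass the test. Open circles are bounds for genes not well above background in one group and black bars are list medians, which run from -5.27 for the stress keratins and SPRR family to 3.48 for the simple and mucosal epithelial keratins.

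Targets and feedback regulators of the ERK kinase cascade, which acts downstream of Ras, rose together. Of 22 tested, 19 rose, 1 fell and 2 did not pass, and adjusted over the list alone 19 rose and 1 fell. Dusp6 and Dusp4, phosphatases that inactivate MAP kinases, rose by 1.66 (SE 0.10) and 3.00 (SE 0.15). Spry1 and Spred3, which restrain Ras signalling, rose by 2.65 (SE 0.07) and 3.67 (SE 0.11). These 4 encode inhibitors of the cascade. Myc, a growth-promoting transcription factor, changed by -0.85 (SE 0.08). The list mean was 1.57, or 1.48 with Spry4 at its bound, and 1.58 with slide as a block, 1.55 on slide 1 and 1.63 on slide 2. The competitive test camera, which sets the list against all other genes, gave adjusted p = 5.12e-07, against adjusted p = 0.112 with an estimated correlation. Of 32 lists, camera called 19 with its preset correlation, and of these only the S phase list passed with an estimated correlation. With the slide block and the estimated correlation together, a setting chosen after the data were seen, it called 0. An exact permutation test of each list's mean over the 35 splits of the arrays gave p = 0.0286, the smallest it can give, for 25 lists, with 0.0366 after Benjamini-Hochberg adjustment. In each of these, all 4 Ras means lay on one side of all 3 Vector means. The splits exchange arrays freely between the slides, so this p takes no account of slide. Splits kept within slides were not tested, and would be too few for any list to reach a p below 0.05.

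Ligands of the EGF receptor moved both ways, with 5 of 7 higher and 2 lower, and the same counts adjusted over the list alone. Areg, Hbegf and Btc rose by 3.36 (SE 0.28), 2.68 (SE 0.14) and 1.89 (SE 0.11), and Tgfa by 1.35 (SE 0.13). Epgn changed by -4.20 (SE 0.16) and Nrg1, which binds the related receptors ErbB3 and ErbB4, by -1.34 (SE 0.07). The mean of 0.72 (0.76 with slide as a block, 0.74 on slide 1, 0.81 on slide 2) did not stand out by camera, with adjusted p = 0.196, and adjusted p = 0.593 with an estimated correlation.

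Cell cycle genes were far lower in Ras, while inhibitors of cyclin-dependent kinases moved in opposite directions. Cdkn2a, which encodes the tumour suppressors p16Ink4a and p19Arf, rose by 3.38 (SE 0.17, adjusted p = 7.39e-06), from 2.89 ± 0.30 (SD, n = 3) to 6.27 ± 0.21 (SD, n = 4). Its probe lies on chromosome 4 from 88920405 to 88920464, and a second probe gave 3.80. With slide as a block the change was 3.44, with 3.39 on slide 1 and 3.53 on slide 2. Its neighbour Cdkn2b, which encodes p15Ink4b, rose by 2.17 (SE 0.12), and Cdkn1c, which encodes p57Kip2, by 2.44 (SE 0.18). Cdkn2d, Cdkn1b and the pocket protein gene Rbl1 changed by -1.25 (SE 0.07), -1.03 (SE 0.09) and -1.59 (SE 0.10), with -1.46 at a second Cdkn1b probe. Cdkn1a, which encodes p21, gave 0.37 (SE 0.18, adjusted p = 0.143), and with slide as a block 0.45 (adjusted p = 0.000965), with 0.48 on slide 1 and 0.39 on slide 2, and its alternatives ranged in adjusted p from 0.000965 to 0.449. The Cdkn1a probes gave 0.22 to 0.67. Of the 10 genes of this list, which holds pocket protein genes as well, 3 rose and 3 fell, or 3 and 4 adjusted over the list alone. The members ran from -3.25, for a gene not named here, to 3.38. Their mean was 0.14 (0.19 with slide as a block, 0.27 on slide 1, 0.05 on slide 2) and their median 0.05, while the camera direction was the opposite, down, with adjusted p = 0.914, and adjusted p = 0.966 with an estimated correlation. With 1 array left out the mean ran from -0.005 to 0.205. Lmnb1, the nuclear lamina protein lamin B1, gave -0.36 (SE 0.19, adjusted p = 0.183), with -0.17 on slide 1 and -0.69 on slide 2. Without Vector replicate 3 it gave -0.61 (adjusted p = 0.00431), where its alternatives ranged from 0.00431 to 0.647. Trp53, the p53 gene, gave 0.14 (SE 0.19, adjusted p = 0.611).

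**Figure D3:**
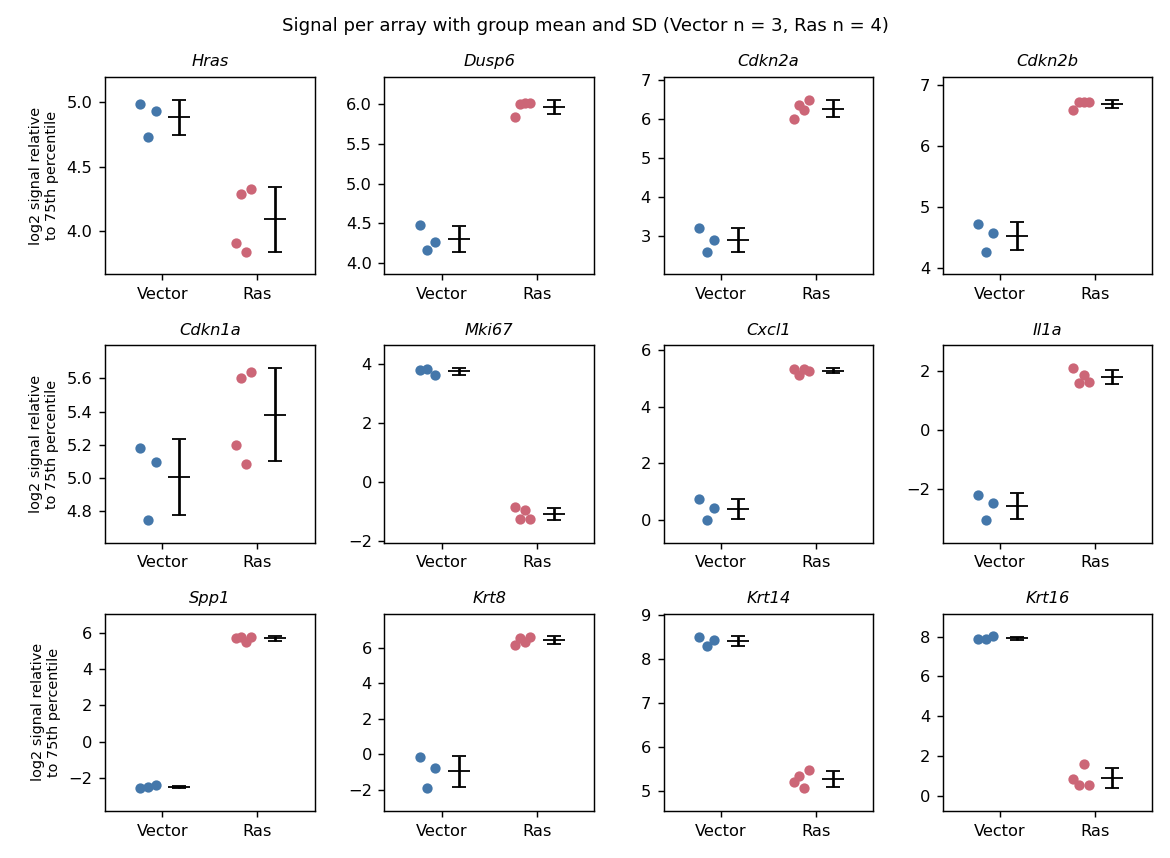
Log2 signal relative to the 75th percentile of each array for 12 genes, with a point per array (Vector n = 3, Ras n = 4) and the group mean with its SD in black; vertical axes differ between panels. Cdkn2a lay at 2.89 ± 0.30 in Vector and 6.27 ± 0.21 in Ras, Mki67 at 3.75 ± 0.11 and -1.08 ± 0.21, and the ranges of Cdkn1a overlapped.

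All 36 genes of mitosis and the G2 phase fell, also adjusted over the list alone. Mki67, the proliferation antigen, changed by -4.83 (SE 0.13, adjusted p = 6.34e-07), with -4.87 when slide is a block, -4.96 on slide 1 and -4.74 on slide 2. Ccna2, the gene of cyclin A2, changed by -4.43 (SE 0.09), Cdc20, an activator of the anaphase-promoting complex, by -3.92 (SE 0.08) and Aurka, a spindle kinase, by -3.22 (SE 0.08). The mean was -3.50, or -3.35 with members at their bound, and -3.53 with slide as a block, -3.66 on slide 1 and -3.33 on slide 2. The list had a camera adjusted p = 4.9e-24, and adjusted p = 0.112 with an estimated correlation. Of 34 DNA replication and S phase genes, 0 rose and 31 fell, or 32 adjusted over the list alone. E2f2, an S phase transcription factor, changed by -4.55 (SE 0.08), the primase gene Prim1 by -3.86 (SE 0.08) and Uhrf1, which maintains DNA methylation, by -2.57 (SE 0.07). Their mean was -1.84 (-1.84 with slide as a block, -1.85 on slide 1, -1.82 on slide 2), with adjusted p = 6.03e-18 by camera and adjusted p = 0.0279 with an estimated correlation.

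Of 26 p53 targets, 13 rose and 4 fell, or 14 and 4 adjusted over the list alone. Gadd45a, a growth arrest and DNA damage gene, rose by 3.71 (SE 0.12), and Mdm2, the ligase that marks p53 for destruction, by 1.40 (SE 0.15). The death receptor gene Tnfrsf10b rose by 1.22 (SE 0.09), whereas the death receptor gene Fas changed by -0.59 (SE 0.09) and Sesn1 by -1.02 (SE 0.12). The mean was 0.54 (0.57 with slide as a block, 0.53 on slide 1, 0.62 on slide 2), with camera adjusted p = 0.0208, and adjusted p = 0.593 with an estimated correlation. Without Vector replicate 2 the mean was 0.47 with adjusted p = 0.0591, where the alternatives ranged from 0.00121 to 0.593.

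Secreted factors that senescent cells are known for changed widely. Of 25 such cytokines and chemokines tested, 17 rose and 7 fell, also adjusted over the list alone. Il1a, the alarm cytokine interleukin 1 alpha, rose by 4.35 (SE 0.22), the neutrophil chemokine gene Cxcl1 by 4.86 (SE 0.17) and the macrophage growth factor gene Csf1 by 3.40 (SE 0.11), with up to 4.22 at its other probes. Csf3, the granulocyte colony-stimulating factor, was at least 63.0-fold higher. Il18, Il11 and the chemokine gene Cxcl12 changed by -1.97 (SE 0.16), -1.56 (SE 0.14) and -3.12 (SE 0.09), with -1.42 at a second Cxcl12 probe. Il6, a main cytokine of this class, was not well above background on any array, and Il1b was so on 2 Ras arrays and 0 Vector arrays, so neither was tested. The mean was 1.80, or 1.71 with members at their bound, and 1.83 with slide as a block, 1.73 on slide 1 and 1.98 on slide 2. Set against all other genes, the list had adjusted p = 0.00239, and adjusted p = 0.354 with an estimated correlation. Of the leukocyte markers, 6 of 11 rose as well, with a mean of 1.39.

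Among 28 secreted proteases, their inhibitors and matrix proteins, 16 rose and 6 fell, or 17 and 6 adjusted over the list alone. Beside Spp1 and Mmp9, the interstitial collagenase gene Mmp1a was at least 52.1-fold higher. Igfbp2, also of this list, had its largest fall, at -7.42. Timp3, an inhibitor of metalloproteinases, and Serpinb2, an inhibitor of plasminogen activators, changed by -3.89 (SE 0.12) and -3.14 (SE 0.08). The mean was 1.63, or 1.46 with members at their bound, and 1.63 with slide as a block and on slide 1 and slide 2 alike. Its test by camera gave adjusted p = 0.00191, and adjusted p = 0.112 with an estimated correlation. Over members well above background on all 7 arrays, the mean was 0.75 with adjusted p = 0.0531, where the alternatives ranged from 2.03e-06 to 0.143. The fibroblast markers moved both ways, 6 of 18 higher and 9 lower.

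Lysosomal genes were modestly higher in Ras. Of 24, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone. Glb1, the lysosomal beta-galactosidase used as a stain for senescent cells, rose by 0.61 (SE 0.13, adjusted p = 0.00725), but gave adjusted p = 0.0503 with median centring, where its alternatives ranged from 0.00021 to 0.104. The hydrolase genes Gusb and Hexa rose by 1.61 (SE 0.07) and 1.19 (SE 0.08) and the cholesterol carrier gene Npc2 by 0.93 (SE 0.09), whereas Ctsa, the protective protein cathepsin A, changed by -0.36 (SE 0.08). A second Ctsa probe gave -0.08 and the mean of both -0.22 (adjusted p = 0.139), where its alternatives ranged from 0.00233 to 0.157. The mean was 0.53 (0.56 with slide as a block, 0.52 on slide 1, 0.62 on slide 2), with camera adjusted p = 0.00122, and adjusted p = 0.519 with an estimated correlation.

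The differentiation programme of the epidermis was lower in Ras. Of 20 genes of the spinous layer, 1 rose and 18 fell, also adjusted over the list alone. Krt1, a keratin of differentiating cells, was at least 36.0-fold lower, or 23.9-fold without Vector replicate 2, and its partner Krt10 changed by -1.84 (SE 0.33), with -4.99 at a second probe. Dmkn, dermokine, changed by -5.70 (SE 0.08), and Dsg1b, a desmosomal cadherin, was at least 16.5-fold lower. The member that rose was the receptor gene Notch3, by 0.56 (SE 0.11), but with adjusted p = 0.0882 on slide 2 alone, where its alternatives ranged from 0.00127 to 0.0882. The mean was -4.43, or -3.95 with members at their bound, and -4.45 with slide as a block, -4.26 on slide 1 and -4.74 on slide 2. Camera gave adjusted p = 3.67e-11, and adjusted p = 0.112 with an estimated correlation. The melanocyte markers moved the same way, 9 of 12 lower with a mean of -2.17.

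Of 35 genes of the cornified envelope and granular layer, 2 rose and 28 fell, also adjusted over the list alone. Beside Flg and Cdsn, Abca12, the lipid transporter of lamellar granules, changed by -3.75 (SE 0.07). The members that rose were both late cornified envelope genes, Lce1g by 3.83 (SE 0.14) and Lce1c by 1.69 (SE 0.20), but a second Lce1c probe gave -6.52 and the mean of both probes -2.42. The brighter probes of Flg2 and Alox12b, singled out after their values were seen, gave 0.02 and 0.25, against -4.26 and -2.13 at other probes. The mean was -3.73, or -3.38 with members at their bound, and -3.78 with slide as a block, -3.55 on slide 1 and -4.12 on slide 2. The list had a camera adjusted p = 2.24e-12, and adjusted p = 0.212 with an estimated correlation. All 15 stress keratin and SPRR genes fell, also adjusted over the list alone. The smallest fall was that of Sprr2a2, at -0.27 (adjusted p = 0.0367), with -4.16 at the lowest of its 3 probes. Krt6a and Krt6b, partners of Krt16 in activated epidermis, changed by -5.27 (SE 0.12) and -5.03 (SE 0.08), with -8.18 at a second Krt6b probe. Their mean was -5.18, or -4.67 with members at their bound, and -5.22 with slide as a block, -5.07 on slide 1 and -5.46 on slide 2. Set against all other genes, the list had adjusted p = 1.67e-11, and adjusted p = 0.112 with an estimated correlation.

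Many of these genes sit in a cluster on chromosome 3. Between the outermost envelope and SPRR genes of the lists, from 91884206 to 93252912, 64 genes were tested, of which 7 rose, 40 fell and 17 did not pass, with a median of -3.43. Within the Lce1 genes, Lce1g, Lce1h and Lce1i rose by 3.83, 3.15 and 3.40, each in every scaling tried, while the neighbouring Lce1a1, Lce1b and Lce1d fell. Lce1g and Lce1h rest on 1 probe each, so the scalings share their probes. The 2 probes of Lce1a2 gave 1.12 and -2.56 and those of Lce1c 1.69 and -6.52, so a probe here may read another Lce1 gene. This region and the Lce1 genes that rose in it were singled out after their values were seen.

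**Figure D4:**
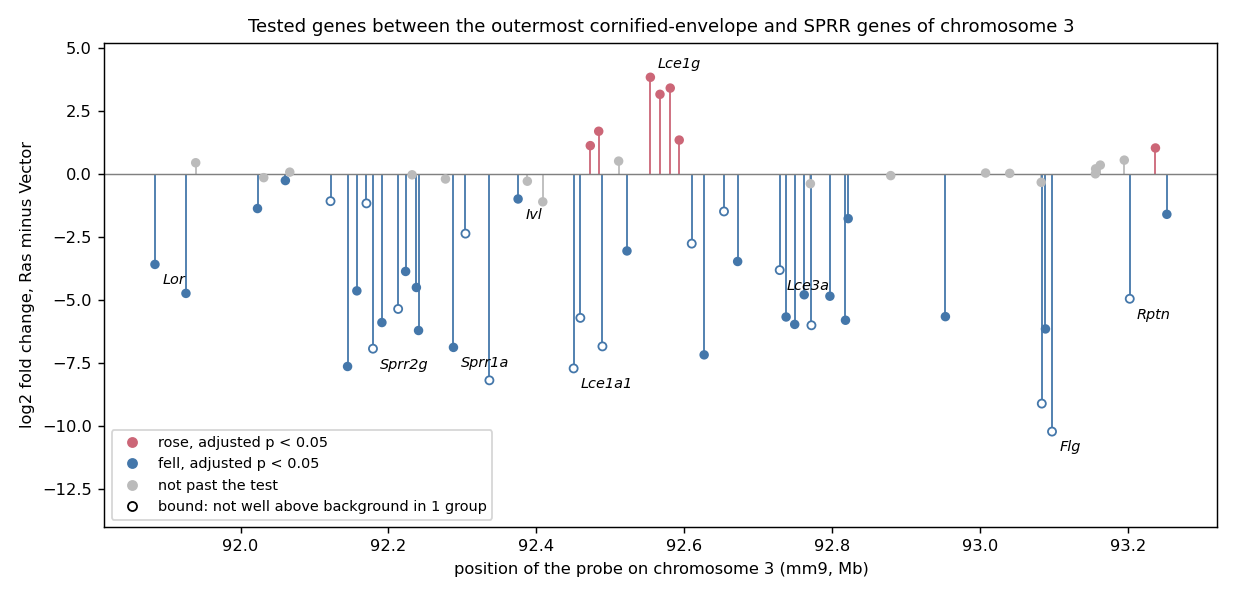
Log2 fold change, Ras minus Vector (vertical axis, 3 Vector and 4 Ras arrays), of the 64 tested genes of the chromosome 3 cluster by probe position in Mb of mm9 (horizontal axis), with open circles for bounds. Most Sprr and Lce3 genes and Flg lie below 0, and Lce1g at 3.83 stands among the few that rose.

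Keratins of other epithelia moved in both directions. Of 8 simple and mucosal keratins, 5 rose and 3 fell, also adjusted over the list alone. Beside Krt8 and Krt18, Krt7 rose by 3.72 (SE 0.20) and Krt20, a keratin of intestinal epithelium, was at least 24.6-fold higher. Krt13, Krt23 and Krt80 changed by -2.96 (SE 0.10), -6.40 (SE 0.39) and -1.14 (SE 0.11), with -4.27 at a second Krt13 probe. Krt23 was well above background on only 2 of the 4 Ras arrays, and its alternatives ran from -6.92 to -4.69. The mean of 2.07, or 1.83 with Krt20 at its bound, was 2.12 with slide as a block, 2.02 on slide 1 and 2.28 on slide 2. Its test by camera gave adjusted p = 0.322, and adjusted p = 0.623 with an estimated correlation.

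Of 22 basal keratinocyte genes, 6 rose and 14 fell, also adjusted over the list alone. Krt14, Krt5 and Krt15, the keratins of the basal layer, changed by -3.13 (SE 0.12), -1.89 (SE 0.12) and -5.31 (SE 0.14), with -3.68 at a second Krt5 probe. Trp63, the epidermal master regulator p63, changed by -2.83 (SE 0.08), with -0.31 at a second probe, and Col17a1, a hemidesmosome collagen, by -3.11 (SE 0.07). The integrin genes Itga2 and Itga3 rose by 1.67 (SE 0.14) and 1.80 (SE 0.16). The mean was -0.81 (-0.80 with slide as a block, -0.75 on slide 1, -0.89 on slide 2), with camera adjusted p = 0.00459, and adjusted p = 0.306 with an estimated correlation. Of 25 desmosome and junction genes, 13 rose and 11 fell, also adjusted over the list alone. Dsg3, Dsc3 and Dsp, components of epidermal desmosomes, changed by -2.95 (SE 0.18), -2.42 (SE 0.08) and -2.30 (SE 0.09). Cldn7, a tight junction claudin, rose by 3.42 (SE 0.29), the desmosomal plakophilin gene Pkp2 by 1.11 (SE 0.08) and Ctnnb1, beta-catenin, by 0.75 (SE 0.07). The median of this list was 0.42, opposite in sign to its mean of -0.14 (-0.13 with slide as a block, -0.12 on slide 1, -0.14 on slide 2) and to the camera direction, with adjusted p = 0.992, and adjusted p = 0.994 with an estimated correlation.

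Alarmins and antimicrobial genes were split. Of 18 tested, 5 rose and 11 fell, also adjusted over the list alone. Tslp, a cytokine that epithelia release in allergy, and S100a9, a calgranulin subunit, changed by -4.53 (SE 0.09) and -3.82 (SE 0.07). Il23a, a subunit of interleukin 23, rose by 4.95 (SE 0.32), or 3.26 to 5.50 over its alternatives, but was well above background on only 2 of the 3 Vector arrays. Saa3, an acute phase protein, was at least 2.77-fold higher. The mean was -1.81, or -1.40 with members at their bound, and -1.80 with slide as a block, -1.77 on slide 1 and -1.84 on slide 2. Camera gave adjusted p = 0.00191, and adjusted p = 0.112 with an estimated correlation. Over members well above background on all 7 arrays the mean was -0.45 with adjusted p = 0.0696, where the alternatives ranged from 2.1e-08 to 0.144.

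Of 20 NF-kB targets, 13 rose and 4 fell, also adjusted over the list alone. Tnfaip2 rose by 2.80 (SE 0.09). Nfkbie and Tnfaip3, which both hold NF-kB signalling back, rose by 1.92 (SE 0.09) and 1.92 (SE 0.10). Ptgs2, the inducible cyclooxygenase, changed by -1.39 (SE 0.08), Icam1, a leukocyte adhesion molecule, by -0.49 (SE 0.09) and Ripk2 by -0.46 (SE 0.08). On slide 2 alone Icam1 and Ripk2 had adjusted p = 0.134 and 0.0604, where their alternatives ranged from 0.00352 to 0.134 and 0.00117 to 0.0729, and Icam1 had 0.0511 with median centring. The mean was 1.04, or 0.93 with a member at its bound, and 1.05 with slide as a block, 1.04 on slide 1 and 1.06 on slide 2. The list had a camera adjusted p = 0.00297, and adjusted p = 0.173 with an estimated correlation. Of 29 interferon response genes, 17 rose and 2 fell, or 18 and 2 adjusted over the list alone. Oasl2, an antiviral protein, and Usp18, which dampens interferon signalling, rose by 3.89 (SE 0.20) and 3.97 (SE 0.19), and the immunoproteasome gene Psmb8 by 1.98 (SE 0.11). Mx1, an antiviral GTPase, changed by -2.50 (SE 0.42) and Ifit2 was at least 1.59-fold lower. The mean was 1.18 (1.19 with slide as a block, 0.98 on slide 1, 1.49 on slide 2), or 1.20 with Ifit2 at its bound. Set against all other genes, the list had adjusted p = 0.000287, and adjusted p = 0.401 with an estimated correlation. The leukocyte markers rose beside both lists, 6 of 11 with a mean of 1.39.

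Of 23 TGF-beta targets, 14 rose and 6 fell, also adjusted over the list alone. Ltbp3, a latent TGF-beta binding protein, rose by 3.84 (SE 0.10), the matricellular gene Ccn2 by 2.42 (SE 0.11), Tgfb1 itself by 1.11 (SE 0.17) and Skil, a repressor of this pathway, by 1.73 (SE 0.07). Tgfbi, a secreted matrix protein, changed by -4.75 (SE 0.25), and Id2 and Id1, inhibitors of helix-loop-helix factors, by -2.42 (SE 0.14) and -1.34 (SE 0.09). The mean was 0.69 (0.71 with slide as a block, 0.72 on slide 1, 0.69 on slide 2), with camera adjusted p = 0.0133, and adjusted p = 0.401 with an estimated correlation. On slide 2 alone the adjusted p was 0.0554, where the alternatives ranged from 3.06e-05 to 0.401. Of 13 Notch pathway genes, 2 rose and 7 fell, also adjusted over the list alone. The ligand genes Jag2 and Dll1 and the receptor gene Notch1 changed by -2.49 (SE 0.07), -2.57 (SE 0.11) and -1.37 (SE 0.10), with -2.00 at a second Notch1 probe, and Rbpj, the DNA-binding partner of Notch, rose by 1.38 (SE 0.09). The mean of -0.62 (-0.62 with slide as a block, -0.51 on slide 1, -0.78 on slide 2) had a camera adjusted p = 0.0641, and adjusted p = 0.354 with an estimated correlation. Without Vector replicate 1 the Notch mean was -0.66 with adjusted p = 0.0431, where the alternatives ranged from 3.06e-05 to 0.392. Of 14 Wnt pathway genes, 6 rose and 4 fell, also adjusted over the list alone. Tcf7, a Wnt effector, rose by 2.04 (SE 0.13), with 2.96 at a second probe, and Lef1, another, rose from signals not well above background in Vector. Sfrp2 and Sfrp1, secreted Wnt antagonists, went apart, at least 7.06-fold higher and by -1.90 (SE 0.13), and the negative regulators Rnf43 and Apcdd1 changed by -1.10 (SE 0.08) and -1.45 (SE 0.16). The mean was 1.08, or 0.81 with members at their bound, and 1.08 with slide as a block, 1.14 on slide 1 and 0.99 on slide 2. Its test by camera gave adjusted p = 0.567, and adjusted p = 0.806 with an estimated correlation.

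Of the metabolic lists, camera called glycolysis and ribosome biogenesis, but neither with an estimated correlation (adjusted p = 0.354 for both). Of 20 glycolysis genes, 2 rose and 10 fell, also adjusted over the list alone. Slc16a3, a lactate exporter, changed by -3.73 (SE 0.28), Ldha, lactate dehydrogenase A, by -0.90 (SE 0.07) and Pfkp, a phosphofructokinase, by -2.09 (SE 0.09), with -0.26 at a second Pfkp probe. The hexokinase genes Hk1 and Hk2 rose by 0.66 (SE 0.11) and 0.73 (SE 0.09), Hk1 with adjusted p = 0.0527 on slide 2 alone, where its alternatives ranged from 0.000616 to 0.0601. The mean was -0.50 (-0.50 with slide as a block, -0.45 on slide 1, -0.59 on slide 2), with camera adjusted p = 0.0201, and adjusted p = 0.354 with an estimated correlation. On slide 1 alone the adjusted p was 0.0794, with quantile normalization 0.0779 and with the authors' processed values 0.091, where the alternatives ranged from 0.000104 to 0.457. Of 21 ribosome biogenesis and Myc target genes, 1 rose and 12 fell, or 1 and 13 adjusted over the list alone. The RNA polymerase I subunit gene Polr1b and the nucleolar genes Nolc1 and Nop56 changed by -0.79 (SE 0.08), -0.73 (SE 0.11) and -0.62 (SE 0.07), and Odc1, the enzyme that starts polyamine synthesis, rose by 0.52 (SE 0.08). The mean was -0.37 (-0.36 with slide as a block, -0.35 on slide 1, -0.36 on slide 2), with camera adjusted p = 0.00287, and adjusted p = 0.354 with an estimated correlation.

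Camera did not call the other metabolic and stress lists. Of 26 oxidative phosphorylation genes, 1 rose and 5 fell, or 1 and 4 adjusted over the list alone, with a mean of -0.08 (-0.06 with slide as a block, -0.08 on slide 1, -0.01 on slide 2). The complex I genes Ndufa4 and Ndufb5 changed by -0.50 (SE 0.08) and -0.36 (SE 0.07), with -0.51 at a second Ndufb5 probe, and Sdhc of complex II gave 0.43 (SE 0.10). None of the 3 passed on slide 2 alone, with adjusted p = 0.0661, 0.111 and 0.0918, where their alternatives ranged from 0.000459 to 0.069, 0.00189 to 0.128 and 0.00475 to 0.129. Sdhc did not pass on slide 1 alone either (adjusted p = 0.055), nor did Ndufb5 and Sdhc with median centring (0.0883 and 0.0892). Camera gave adjusted p = 0.322, and adjusted p = 0.834 with an estimated correlation. Of 23 cholesterol synthesis genes, 5 rose and 7 fell, or 6 and 7 adjusted over the list alone, with a mean of -0.07 (-0.08 with slide as a block, 0.03 on slide 1, -0.24 on slide 2). Insig1, a feedback regulator, rose by 1.13 (SE 0.13), and the enzyme genes Mvk and Lss changed by -0.82 (SE 0.10) and -0.70 (SE 0.11), with -0.53 at a second Mvk probe. The list had a camera adjusted p = 0.487, and adjusted p = 0.834 with an estimated correlation. Of 20 fatty acid and PPAR genes, 7 rose and 7 fell, also adjusted over the list alone. Fabp5, the epidermal fatty acid binding protein, changed by -4.17 (SE 0.10) and Elovl4, a very long chain elongase, by -2.83 (SE 0.09), while the acyl-CoA ligase gene Acsl4 rose by 3.77 (SE 0.09). The mean was -0.39 (-0.40 with slide as a block, -0.35 on slide 1, -0.46 on slide 2) and the median 0.17, of opposite sign, with camera adjusted p = 0.914 in the direction of the mean, and adjusted p = 0.94 with an estimated correlation.

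Of 24 unfolded protein and amino acid stress genes, 7 rose and 5 fell, also adjusted over the list alone. The stress regulators Trib3 and Atf3 rose by 1.69 (SE 0.09) and 1.16 (SE 0.10), and Psat1 and Phgdh, enzymes of serine synthesis, changed by -1.55 (SE 0.08) and -0.78 (SE 0.13). The mean was 0.13 (0.14 with slide as a block, 0.14 on slide 1, 0.15 on slide 2), with camera adjusted p = 0.518, and adjusted p = 0.834 with an estimated correlation. Of 22 NRF2 and oxidative stress genes, 8 rose and 7 fell, or 10 and 7 adjusted over the list alone. The metallothionein genes Mt1 and Mt2, which bind metals, rose by 2.89 (SE 0.13) and 3.20 (SE 0.14), while the glutathione genes Gpx2, Gsta4 and Gclc changed by -3.83 (SE 0.12), -2.32 (SE 0.13) and -1.45 (SE 0.08). The mean was 0.06 (0.08 with slide as a block, 0.01 on slide 1, 0.18 on slide 2), with camera adjusted p = 0.88, and adjusted p = 0.94 with an estimated correlation. With 1 array left out the mean ran from -0.008 to 0.1.

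Markers of other cell types that a skin preparation can hold were measured alongside. Of 18 fibroblast markers, 6 rose and 9 fell, also adjusted over the list alone. Postn, periostin, and Vim, vimentin, which cultured epithelial cells can also express, rose by 4.68 (SE 0.08) and 2.05 (SE 0.11). The collagen genes Col1a2 and Col1a1 changed by -2.22 (SE 0.12) and -0.78 (SE 0.15), the latter with adjusted p = 0.0716 on slide 1 alone, where its alternatives ranged from 0.000628 to 0.0716. The mean was -0.14 (-0.12 with slide as a block, 0.03 on slide 1, -0.35 on slide 2) and the median -1.05, with camera adjusted p = 0.436, and adjusted p = 0.834 with an estimated correlation. Of 12 melanocyte markers, 0 rose and 9 fell, or 1 and 9 adjusted over the list alone. The pigment enzyme genes Tyrp1 and Dct and the regulator gene Mitf changed by -3.75 (SE 0.14), -3.49 (SE 0.12) and -3.36 (SE 0.08). Their mean was -2.17, or -2.07 with a member at its bound, and -2.18 with slide as a block, -2.06 on slide 1 and -2.37 on slide 2. Set against all other genes, the list had adjusted p = 1.93e-05, and adjusted p = 0.212 with an estimated correlation.

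Of 20 leukocyte markers, 11 could be tested, of which 6 rose and 0 fell, or 7 and 0 adjusted over the list alone. H2-Ab1, a class II antigen-presenting molecule, Aif1 and Cd14, both macrophage proteins, rose by 3.59 (SE 0.22), 3.25 (SE 0.18) and 2.54 (SE 0.16). Ptprc, the pan-leukocyte antigen CD45, was not well above background on any array. The mean was 1.39, or 1.18 with members at their bound, and 1.38 with slide as a block, 1.46 on slide 1 and 1.26 on slide 2. Its test by camera gave adjusted p = 0.00525, and adjusted p = 0.112 with an estimated correlation. Of 6 endothelial markers tested, 2 rose and 2 fell, or 2 and 3 adjusted over the list alone. Flt1, a receptor of vascular growth factors, rose by 1.20 (SE 0.15), Pecam1, an endothelial adhesion molecule, changed by -1.32 (SE 0.11), and the mean was -0.23 (-0.23 with slide as a block, -0.14 on slide 1, -0.36 on slide 2). Camera gave adjusted p = 0.674, and adjusted p = 0.806 with an estimated correlation.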

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

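The tests of cell composition and of slides below, and the patterns they weigh, were chosen only after the results were seen.

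Among the 4 Ras arrays, 8 of 231 values examined had an array that stood apart from the other Ras arrays by Dixon's criterion, which chance alone meets in about 1 of 20, or 11.6 here. Values are log2 signals relative to the 75th percentile. Vegfc lay at 2.22 in Ras replicate 3 and Spink5 at -3.92 in Ras replicate 2. In Ras replicate 1, Cdkn2b lay at 6.59 and Dusp6 at 5.83, both below the other Ras arrays. In Ras replicate 4, Sprr1a lay at -0.62 and Saa3 at -2.89, both above the others, and Krt15 at -2.40, below them. The mean of the Wnt list was -1.0 in Ras replicate 4, above the others.

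Differentiation genes were the first pattern weighed. Of 69 spinous, cornified, stress keratin and SPRR genes, 60 fell and 3 rose in Ras, with a median of -4.51. Fewer epithelial cells among the Ras cells would lower basal and junction genes by about as much, but these had a median of -0.319 and 19 of 47 rose, which argues against it as the whole cause. Some of these genes are not restricted to keratinocytes. Of the basal list 14 of 22 fell, among them Krt15 at -5.31, Krt14 at -3.13, Col17a1 at -3.11, Trp63 at -2.83 and Krt5 at -1.89, so fewer keratinocytes as a part of the cause stays open. Of 18 fibroblast markers 9 fell and 6 rose, the latter including Postn at 4.68, Loxl1 at 2.94 and Vim at 2.05. This argues against a shared rise of these markers, but a list that moves both ways cannot exclude some overgrowth of fibroblasts. A difference between the slides is argued against by a mean of -4.25 with slide as a block, -4.05 on slide 1 and -4.56 on slide 2, so an effect of HRasV12 on the differentiation programme may underlie much of the pattern, as a hypothesis found and tested on the same data.

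Leukocyte markers were the second pattern. Of 20 listed, 6 rose, but 9 had no probe well above background on any Ras array, among them the abundant leukocyte genes Ptprc, Tyrobp, Laptm5 and Lyz2, which argues against more leukocytes among the Ras cells. Cd74 and Lyz1 went the other way, well above background on 4 and 3 Ras arrays and on 0 Vector arrays. The labels name no sort that would remove such cells, and 9 of the 20 were well above background on all 3 Vector arrays as well. The mean was 1.381 with slide as a block, 1.459 on slide 1 and 1.262 on slide 2, which argues against a slide difference. Induction of H2-Ab1, Aif1 and Cd14 within the keratinocytes is a candidate explanation that was not tested. Another class II gene of the list, H2-Aa, had no probe well above background on any array.

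Melanocyte markers were the third pattern, with 9 of 12 lower in Ras. Fewer melanocytes among the Ras cells and lower transcription cannot be told apart. The 3 markers that did not fall were Sox10 at 0.27, Tyr at 0.17 and Trpm1 at -0.28, but a second Trpm1 probe gave -3.30 and Sox10 and Tyr each rest on 1 probe above background. A slide difference is argued against by a mean of -2.181 with slide as a block, -2.056 on slide 1 and -2.369 on slide 2.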

How the results depend on the processing

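The only alternative chosen after the results were seen was the slide block together with an estimated correlation. Over the other alternatives except the replicate block, genes that rose numbered 3887 to 7258 and genes that fell 3564 to 6374, against 5374 and 4821. With 1 array left out they numbered 4517 to 5191 and 3905 to 4757. At least 2-fold, 1405 genes rose with the authors' processed values, against 2134, and the counts over all these alternatives ran from 1405 to 2346 higher and 1422 to 2247 lower. The cause of the lower 2-fold count was not tested. Of 199 named genes tested, 178 kept their direction and side of the threshold in every alternative that gave them a value. The filter requiring all 7 arrays gave a value for only 175 of the 199. Among 4155 values of a gene in an alternative, 4096 did so, 51 were no longer past the threshold, 6 newly passed it and 2 reversed. The replicate block accounted for 14 of the 51, slide 2 alone for 13 and median centring for 7. Slide 2 alone lost Notch3, Hk1, Ndufa4, Ndufb5, Sdhc, Icam1, Ripk2 and Ctsa among others, and median centring also lost Ndufb5, Sdhc, Icam1 and Ctsa. Sdhc lost its call on slide 1 alone as well. Ctsa lost its call with the mean of its probes and with the authors' processed values too. The causes were not tested. With 1 array left out, Ndufa9 and Vwf lost their call in some fits and Lmnb1 gained one without Vector replicate 3. Actb reversed with quantile normalization, at 0.177 (adjusted p = 0.0472, over its alternatives 0.0472 to 0.959). Lce1c reversed with the mean of its probes, at -2.418 (adjusted p = 0.000175, over its alternatives 0.00017 to 0.00781), since its 2 probes have opposite signs.

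With the replicate number as a block, 2850 genes rose and 2614 fell. Same-numbered samples all lay on different slides, with correlations of -0.421, -0.557 and -0.494 between their deviations from the group means. Differently numbered pairs on different slides had -0.652 to -0.478, and pairs on the same slide 0.413 to 0.649. The sign followed slide, so these values cannot tell whether the numbers pair the samples. The scanner file names number the samples in a different order, so a replicate number here is only that of the label. Since nothing showed or excluded that the numbers pair the samples, calls lost under the block are not read for or against a weaker effect. Ras replicate 4 has no partner in the block, but leaving it out alone still gave 4765 and 4413 genes. By design the block fits a level for each number, which leaves fewer degrees of freedom, and all its pairs straddle the slides. How much each of these lowered the counts was not tested.

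Lists depended most on whether camera used its preset or an estimated correlation. With an estimated correlation, camera called 1 list in place of 19, and with the slide block as well, 0. Means then stayed close and adjusted p-values rose: 1.571 (0.112) and 1.583 (0.143) for ERK targets, 0.538 (0.593) and 0.565 (0.144) for p53 targets, -3.502 (0.112) and -3.528 (0.181) for mitosis. They were 1.797 (0.354) and 1.83 (0.144) for secreted cytokines, 1.625 (0.112) and 1.63 (0.143) for secreted proteases, and 0.529 (0.519) and 0.561 (0.218) for lysosomal genes. The S phase list had -1.84 (0.116) with both. Lost calls did not follow the size of the estimate alone. Leukocyte markers, at an estimated 0.00071, and alarmins, at -0.04, lay below the preset 0.01. Both still rose in camera adjusted p, from 0.00525 and 0.00191 to 0.112. The shifted simulated list, whose noise was independent between probes, rose as well, from 2.14e-53 to 0.00061. A higher adjusted p with an estimated correlation therefore does not by itself show that members of a list are correlated. The p53 mean ran from 0.466 to 0.584 with 1 array left out, and passed in each such fit except without Vector replicate 2 (0.466, adjusted p = 0.0591), where the cause was not tested. Secreted proteases had 0.749 (adjusted p = 0.0531) over members well above background on all 7 arrays, which leaves out genes dim in Vector such as Mmp9. EGF receptor ligands passed by fry (0.723, adjusted p = 0.0105), as did 7 other lists that camera did not call. Fry asks only whether the members change on average, without setting them against other genes. Lists that move both ways can pass it, such as the desmosome and junction genes (13 higher, 11 lower, fry adjusted p = 0.00291). The correlation of the within-slide fold changes across genes was 0.955 over genes well above background on all arrays, against 0.946.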

Other observations

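All scans of gene families and chromosome windows in this part were chosen only after the data were seen, and so were the tests of other splits of the arrays, except that of the gene lists.

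The Hoxb genes, which encode transcription factors that set position along the body axis, were higher in Ras as a cluster. Of 9 tested, 7 rose and 1 fell, with a mean of 1.02 that ran from 0.97 to 1.08 over the scalings and slide fits. Hoxb8 rose by 2.12 (SE 0.32), Hoxb7 by 1.87 (SE 0.11) and Hoxb4 by 1.82 (SE 0.12). The antisense transcript Hoxb5os changed by -2.13 (SE 0.14), and Hoxb9 gave 0.15 (adjusted p = 0.583) with a sign that flipped between scalings. Camera gave the family adjusted p = 0.0345, and adjusted p = 0.97 with an estimated correlation. Kallikrein genes, whose proteases shed the cells of the skin surface, went the other way. Of 14 Klk genes 0 rose and 9 fell, with a mean of -3.07 (adjusted p = 0.000102, and adjusted p = 0.866 with an estimated correlation) that ran from -3.52 to -2.29 over the scalings and slide fits. Klk7, Klk10 and Klk6 changed by -6.53 (SE 0.35), -5.20 (SE 0.11) and -4.81 (SE 0.22), and Klk13 was at least 50.9-fold lower. The sign of Klk11, at -0.04, flipped between scalings. Of 257 families of at least 8 members scanned, 21 were called, and 0 with an estimated correlation.

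Of 13 matrix metalloproteinase genes 10 rose and 0 fell, with a median of 1.29 and a mean of 3.07 (adjusted p = 7.6e-05, and adjusted p = 0.763 with an estimated correlation). The mean ran from 1.93 with the authors' processed values to 3.21 on slide 1. Serpinb genes, clustered protease inhibitors, had a mean of -2.01 over 18 members, of which 2 rose and 9 fell (adjusted p = 0.00944, and adjusted p = 0.763 with an estimated correlation). Their mean ran from -2.14 on slide 1 to -1.26 with the authors' processed values.

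Windows of 12 neighbouring genes were set against 1000 permutations of gene order, whose smallest share is 0.001. On chromosome 11 from 53796841 to 54560063, 10 of 12 genes rose and 0 fell, with a mean of 2.44 (permutation share 0.001, 1.80 to 2.45 over the scalings and slide fits). The window holds the cytokine genes Csf2 and Il3, which rose by 7.19 (SE 0.70, 5.88 to 8.98 over the scalings and slide fits) and 4.31 (SE 0.40, 2.52 to 4.80), and Pdlim4 and P4ha2, which rose by 6.00 (SE 0.14) and 2.08 (SE 0.09). Acsl6 was at least 15.2-fold higher at its brighter probe, with a fitted change of 2.32 at the other. Csf2 and Il3 were well above background on 2 and 1 of the Vector arrays. The kallikrein genes on chromosome 7 from 50950330 to 51106551 had a mean of -4.03, and the type II keratins on chromosome 15 from 101417748 to 101776658 one of -3.99. Predicted genes on chromosome 14 from 42541982 to 43929384 had a mean of 2.93, but these are near-identical copies that may share a transcript's signal, and the mean was 1.10 with normexp background correction. Chromosome medians ran from -0.01 to 0.10.

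Other splits of the 7 arrays into groups of 4 and 3 were fitted, 35 in all. For the counts of genes, the real split gave 5374 higher and 4821 lower. The highest count in 1 direction from any other split was 1735, from the split that follows the slides. At least 2-fold, the real counts were 2134 and 1977 and the highest other 779, so that 1 of 35 splits, the real one, was as large for each count. That is the smallest share 35 splits can give, and the splits took no account of slide. In the other splits the group difference adds to the spread within groups, so their low counts say little about chance. Chance differences between the samples are therefore not excluded for these counts. Chance is not excluded for the number of lists camera called with its preset correlation, 19 in the real split and 19 at most in the others, with 2 of 35 splits as large.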
